A study of Mus musculus with 16 samples.

How the data were processed

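RNA was measured by poly-A selected sequencing in 16 libraries from mouse colorectal tumours. Per the series description, MC38 cells, a colon carcinoma line of the C57BL/6 strain, were placed in the wall of the descending colon as an MSI (microsatellite instability) or a CIN (chromosomal instability) line. Bone marrow derived dendritic cells were exposed for 30 minutes to 2 µg of DNA taken from MSI or CIN cells, either as free cytosolic DNA or as micronuclei, with a lipid transfection reagent. They were injected into the abdominal cavity on days 1, 6 and 12, and the tumours were collected on day 15. Equal amounts of RNA from 3 biological replicates were combined before sequencing, per the series description. Whether each library is such a pool of its own is not stated, so the p-values measure the spread between these libraries, part of which may be technical. The titles in the labels give 8 groups of 2 libraries. No library from mice given unstimulated dendritic cells was analysed here.

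The authors deposited a table of counts per gene and a table of FPKM values. Per the submitters' processing notes, the tools were fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the build was GRCm39. The gene coordinates in the deposited count table were those of GRCm38: 53499 of 54409 gene identifiers shared with GENCODE M21 had identical coordinates, and the last gene on chromosome 1 ended at 195323493. Coordinates are therefore given as GRCm38. The strand setting of the counting is not given in the sources used here, and the labels describe both a stranded and an unstranded kit, so reads of overlapping genes on opposite strands could not be told apart. The deposited FPKM values were the counts divided by gene length and by 1 total per library, exactly to a relative tolerance of 1e-06, and that total was 0.899 to 1.08 times the sum of the counts. The FPKM values were used for that check alone. Of the columns of each, 4 matched no sample and were not used. Every count belonged to a named gene. The table held 54532 genes, and the total per library ran from 11561955 to 17937501 counts. Of 595 listed genes 593 had a symbol in the files, older symbols included (Mb21d1 for Cgas, Tmem173 for Sting1).

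From the deposited counts, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling, filterByExpr by group (18777 genes kept), a model with 1 mean per group, robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. The comparisons were the tumour, DNA source and DNA form effects over all 16 libraries, their 3 pairwise interactions (halved, so that they are on the scale of a mean difference), the source and form effects within each tumour type, and MSI free DNA against CIN micronuclei within each tumour type. Each fold change is given as log2 with its standard error. Levels are CPM with the TMM factors. The common biological coefficient of variation was 0.43, so gene differences were limited by the spread between libraries more than by counting.

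Gene lists for immune and stromal cell types, other tissues, interferon and cytokine responses, DNA sensing and repair, cell cycle, hypoxia and stress were fixed before the data were examined, 34 in all, as were the comparisons and the rule for named genes. Each of the 32 lists with at least 5 tested members was tested with camera in limma 3.58.1 at the preset correlation of 0.01, adjusted over the lists of 1 comparison. The same lists were tested with an estimated correlation and with fry, which asks whether the members move 1 way on balance and compares them with no other genes. In arbitrary splits of the 16 libraries into 8 and 8, each in a model of the split alone, a median of 11 lists passed camera at the preset correlation. A pass at the preset correlation alone is therefore weak evidence. The mean log2 CPM of each list per library served as its score, compared by an exact permutation test of both tails and adjusted over 38 measures. For the effects over all 16 libraries the labels were permuted within the matched groups. Within a tumour type they were permuted over all 70 arrangements of the 8 libraries, ignoring the groups. Permutation within the matched groups (36 arrangements, or 16 for the replicate numbers) was added for 9 scores after seeing the data. Of protein-coding genes past the threshold with a mean log2 CPM of at least 1 and the same direction in every matched pair of group means, the 8 with the largest rise and the 8 with the largest fall in the tumour, source or form effect were named (4 and 4 in the other comparisons). To these were added up to 4 called members of each list passing camera and 16 fixed genes whatever their result; 1 further fixed gene is not reported here.

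The 2 libraries of a group differed by more than counting noise in all 8 groups (chi-square per degree of freedom 19.9 to 221, Pearson correlation of log2 CPM across genes 0.873 to 0.976). They were treated as separate samples. Deviations from group means of libraries with the same replicate number were correlated in all 6 pairs of groups within MSI tumours (0.396 to 0.796). Among pairs within CIN tumours 2 of 6 were over 0.1 (-0.326 to 0.38), and over all 28 pairs 16 were. The numbers were therefore taken to pair the libraries within MSI tumours, where the pairing comes from the data and not from the labels. The reported fits have no term for this pairing, which entered the fits only in the alternatives with a replicate block.

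Alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, a replicate block, a smooth muscle score as covariate, an additive model, the libraries of a group summed, fits to 1 tumour type, and leaving out each library in turn. A block within each tumour type, colon epithelium and skeletal muscle scores as covariates, and a fit without the 5 libraries highest in skeletal muscle transcripts were chosen after seeing the data. The procedure was tested on simulated data made from the real means and library sizes, with 200 genes changed. The changed genes were drawn from those with a mean over 2 CPM. Each gene and library was drawn independently, without the replicate and tissue patterns of the real libraries. The rates below may therefore not hold for the real data or for genes with lower counts. For the tumour effect, run on 18264 genes, it recovered 50% of 2-fold and 93% of 4-fold changes with 6 false calls. The DNA source effect (18250 genes) gave 61% and 87% with 13 false calls, and the DNA form effect (18304 genes) 53% and 83% with 10. Within MSI tumours the source effect (18286 genes) gave 23% and 75% with 6 false calls, the form effect (18291 genes) 17% and 69% with 6, and MSI free DNA against CIN micronuclei (18285 genes) 3% and 50% with 0. The form effect in CIN tumours (18275 genes) gave 29% and 74% with 9. The file checks and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.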

Results

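The data were gene counts from 16 libraries of tumours grown from MC38 colon carcinoma cells in the colon wall of mice. The tumour was the MSI or the CIN line, and the mice received dendritic cells that had taken up DNA from MSI or CIN cells, as free cytosolic DNA or as micronuclei. Micronuclei are small membrane-enclosed bodies that hold chromosome fragments outside the main nucleus. Each of the 8 combinations had 2 libraries, and the totals ran from 11561955 to 17937501 counts. The series asks how cytosolic DNA made by cells that lack mismatch repair bears on immunity against the tumour.

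Marker genes of colon epithelium and muscle differed widely between libraries, and whether they came from host tissue or from the tumour cells was not tested. The first principal component of log2 CPM, the main axis of difference between the libraries, held 53.9% of the variance. Its Pearson correlation was -0.972 with the colon epithelium score and 0.649 with the skeletal muscle score. The colon epithelium list, which holds genes such as Epcam, Muc2 and Car1, had a mean log2 CPM of 7.04 ± 1.66 in MSI and 6.35 ± 1.83 in CIN tumours (SD, n = 8 each, exact permutation p = 0.489, adjusted 0.563). Within MSI tumours the replicate 2 libraries had 8.35 ± 0.27 and the replicate 1 libraries 5.73 ± 1.32 (SD, n = 4 each, exact permutation p = 0.0286 over arrangements that ignore the groups, adjusted 0.0679, and p = 0.125 within the groups, each the smallest possible). The smooth muscle list moved with it, at 5.60 ± 0.55 in replicate 2 and 3.48 ± 0.44 in replicate 1 (n = 4 each, same exact permutation p-values). In these libraries the mitochondrial share of counts was 2.29 to 3.68% in replicate 2 and 1.43 to 1.71% in replicate 1. The cell cycle score was 6.32 to 6.60 in replicate 2 and 6.87 to 7.19 in replicate 1. Skeletal muscle genes such as Acta1 and Myh4 stood high in 5 libraries. These were MSI tumour CIN micronuclei 1 (5.66), CIN tumour MSI micronuclei 1 and 2 (4.42 and 4.05), CIN tumour CIN free 2 (4.06) and CIN tumour MSI free 2 (3.18), while the other libraries lay between -1.29 and 0.75.

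**Figure D1:**
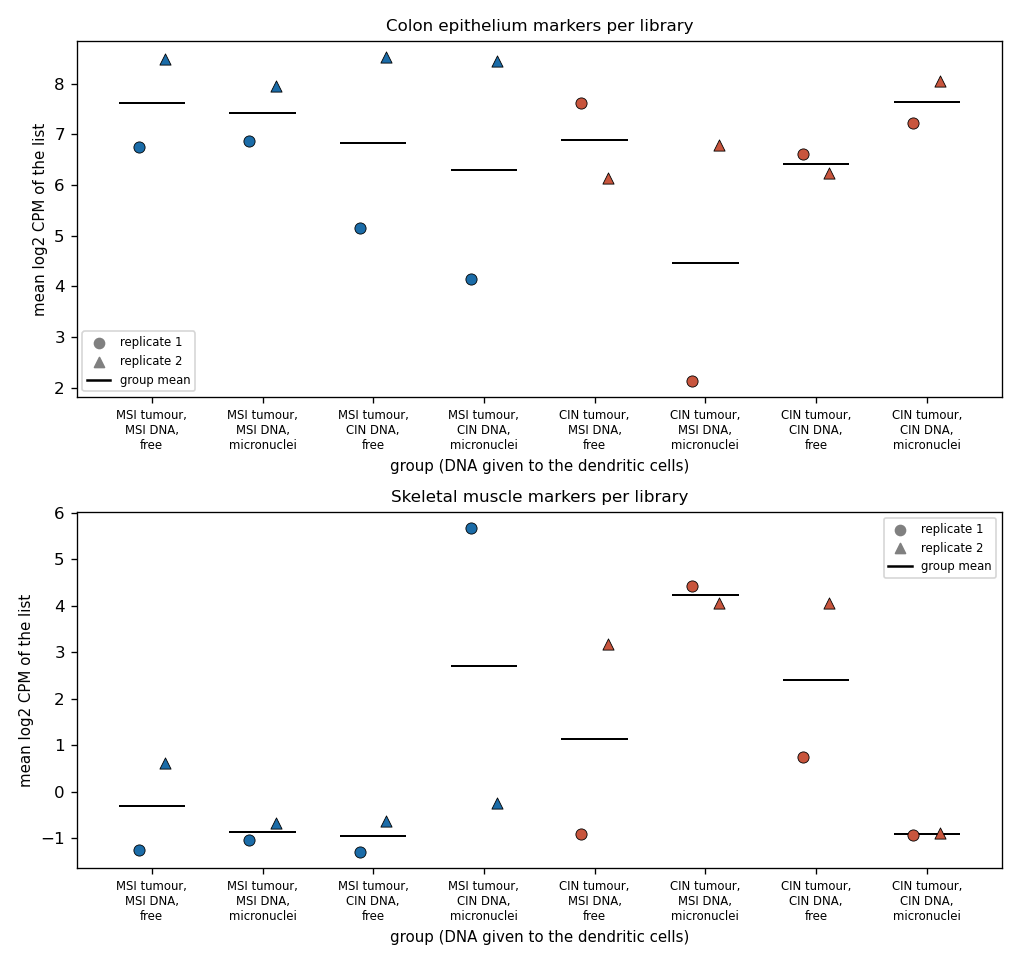
Mean log2 CPM of the colon epithelium list (upper panel) and the skeletal muscle list (lower panel) in each library, by group; circles are replicate 1, triangles replicate 2, and lines are the means of the 2 libraries. Replicate 2 of every MSI tumour group has the higher colon epithelium score, and 5 libraries stand at 3.18 to 5.66 for skeletal muscle.

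The tumour comparison asked how MSI tumours differed from CIN tumours over all kinds of DNA. The sources used here name 1 line per tumour type. The kind of instability therefore cannot be told apart from other differences between the lines. Transcripts of the follistatin gene Fst, whose product binds activin, were 11.9-fold higher in MSI tumours, at 59.8 ± 16.5 against 5.03 ± 1.68 CPM (SD, n = 8 each, log2 fold change 3.58 ± 0.30 SE, edgeR with Benjamini-Hochberg adjusted p = 2.59e-04). Amigo2, which encodes an adhesion protein, rose from 30.8 ± 7.24 in CIN to 199 ± 62.9 CPM in MSI tumours. Ngfr, the low-affinity receptor of nerve growth factor, was 28.2-fold lower in MSI tumours, at 2.82 ± 1.497 against 79.7 ± 24.7 CPM (log2 fold change -4.82 ± 0.44). Sh3tc2 also fell, from 22.3 ± 5.17 to 1.69 ± 0.34 CPM. In all, 435 genes were higher and 654 lower in MSI tumours of 18777 tested (edgeR, Benjamini-Hochberg).

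Among protein-coding genes with a mean log2 CPM of at least 1 and the same direction in every matched pair of group means, the other largest rises were in Cdh26 (log2 fold change 4.94), Omd (4.38), the mast cell tryptase gene Tpsb2 (3.94), Apod (3.11), Gxylt2 (2.88) and the tight junction gene Cldn1 (2.83). The largest falls after Ngfr were in Esx1 (-3.88), the neuritin gene Nrn1 (-3.85), Gm10392 (-3.78), Wnt10a (-3.73), Gm9732 (-3.57) and Dach2 (-3.54). In GRCm38 coordinates Fst (ENSMUSG00000021765) lies on chromosome 13 from 114452290 to 114458951, and Ngfr (ENSMUSG00000000120) on chromosome 11 from 95568818 to 95587735. Amigo2 (ENSMUSG00000048218) lies on chromosome 15 from 97244125 to 97247287.

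**Figure D2:**
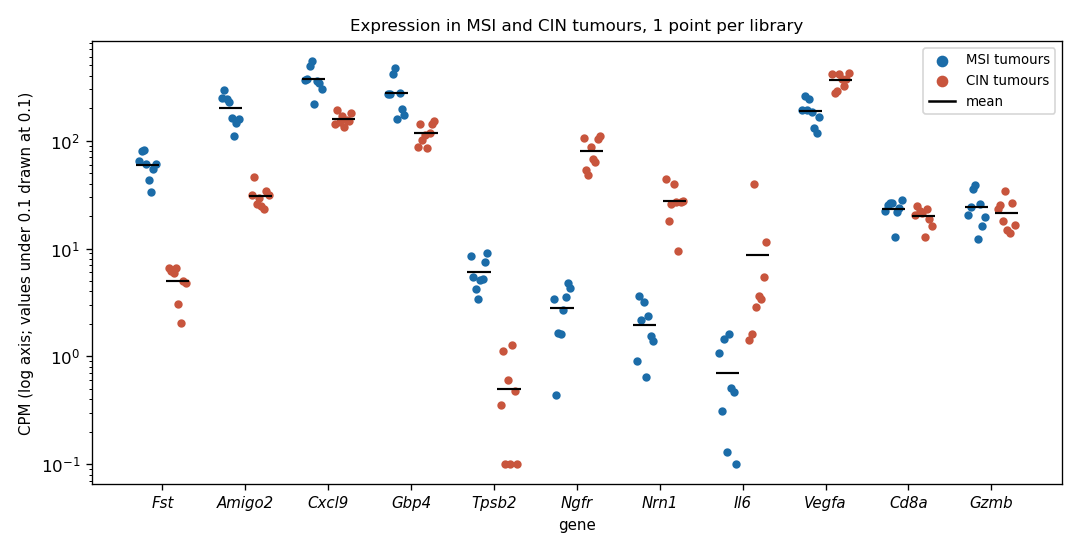
CPM of 11 genes on a log axis, 1 point per library, for the 8 MSI and the 8 CIN tumour libraries, with lines at the means and values under 0.1 drawn at 0.1. Fst, Amigo2, Cxcl9, Gbp4 and Tpsb2 are higher in MSI tumours, Ngfr, Nrn1, Il6 and Vegfa lower, and Cd8a and Gzmb did not pass the test.

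Genes induced by interferons were among those higher in MSI tumours. Of 34 type I interferon response genes 31 had a positive fold change, and 6 rose, 11 when adjusted over the list alone. Zbp1, a sensor of Z-form nucleic acid, had 102 ± 28.3 against 54.6 ± 8.48 CPM (log2 fold change 0.88). Dhx58 (0.76), Rtp4 (0.68) and Slfn5 (0.52) also passed. The list passed camera (adjusted p = 1.81e-06), but not with an estimated correlation (adjusted p = 0.372 with an estimated correlation). Of 23 interferon gamma response genes 2 rose, also 2 adjusted over the list alone. These were Cxcl9, a chemokine that draws activated T cells, at 375 ± 103 against 159 ± 20.2 CPM (SD, n = 8 each, edgeR adjusted p = 0.00148), and the guanylate-binding protein gene Gbp4 (1.25). That list passed camera with adjusted p = 0.0311 (adjusted p = 0.664 with an estimated correlation).

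Antigen presentation genes moved little. Of 20 MHC class I presentation genes Pdia3 (0.33), Psmb10 (0.53) and Tapbpl (0.45) rose, 4 genes adjusted over the list alone, and the camera call (adjusted p = 0.0252) was lost (adjusted p = 0.664 with an estimated correlation). It also missed the threshold with the replicate number as a block (camera adjusted p = 0.0504). Of 16 MHC class II presentation genes Cd40 (0.65) passed, 3 adjusted over the list alone (camera adjusted p = 0.00372, adjusted p = 0.629 with an estimated correlation). T cell genes were positive in 19 of 20, and B and plasma cell genes in 17 of 17, with 0 passing edgeR's test over all genes or adjusted over the list alone. Both lists passed camera (adjusted p = 0.00856 and 0.00941) and neither did otherwise (adjusted p = 0.664 with an estimated correlation for both). Cd8a had 23.3 ± 4.83 against 20.04 ± 3.96 CPM and Gzmb 24.1 ± 9.13 against 21.5 ± 6.96 CPM (n = 8 each, edgeR adjusted p = 0.398 and 0.755). Among 19 cytotoxic effector genes the receptor gene Klrk1 (0.84) and the chemokine gene Xcl1 (2.37) rose. Xcl1 was low, with 1.65 ± 0.93 against 0.38 ± 0.36 CPM. Both genes of the list also rose adjusted over the list alone. That list passed camera at adjusted p = 0.0491 (adjusted p = 0.664 with an estimated correlation), and did not with the block (camera adjusted p = 0.0694) or with a block within each tumour type (0.0723).

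Mast cell genes had the largest list difference. All 9 tested members were positive and 6 rose, also 6 adjusted over the list alone. Among them were Mcpt2 (log2 fold change 4.20), Cpa3 (4.39), Mcpt4 (3.84) and Tpsb2, the last with 6.05 ± 2.05 against 0.50 ± 0.48 CPM. Mcpt2, Cpa3 and Mcpt4 had 3.30, 2.96 and 3.18 CPM in MSI and 0.37, 0.17 and 0.33 CPM in CIN tumours. Their fold changes thus rest on few counts in CIN tumours. Reads of the near-identical tryptase genes Tpsb2 and Tpsab1 could be split between them. The list passed camera (adjusted p = 1.81e-06, adjusted p = 0.372 with an estimated correlation), and its score differed by exact permutation test (1.47 ± 0.63 against -0.71 ± 0.68, n = 8 each, p = 0.00154, the smallest possible, adjusted 0.0293). Within MSI tumours the mast cell score moved with the colon epithelium score, at 2.01 ± 0.20 in replicate 2 and 0.92 ± 0.28 in replicate 1. Endothelial genes were positive in 15 of 16. Esam (0.75), Pecam1 (0.69), Tie1 (0.78) and Egfl7 (0.76) were among 7 that rose, with 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 6.14e-06, adjusted p = 0.372 with an estimated correlation). Smooth muscle genes were positive in 16 of 18 with 0 called by edgeR, over all genes or over the list alone (camera adjusted p = 0.0491, adjusted p = 0.664 with an estimated correlation).

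Several inflammatory cytokine genes and a neutrophil gene were lower in MSI tumours. Of 24 cytokine and chemokine genes 8 fell and 1 rose, or 11 and 1 adjusted over the list alone. Il6, a pyrogenic cytokine, had 0.70 ± 0.60 against 8.72 ± 13.0 CPM (log2 fold change -3.53), and the CIN mean was 4.27 CPM without CIN tumour MSI free 1. The neutrophil attractants Cxcl2 (-2.24) and Cxcl3 (-2.26) fell, as did Il11 (-1.31), while the monocyte attractant Ccl2 rose (0.74). Of 13 neutrophil genes S100a9 fell (-2.20, 0.47 ± 0.22 against 2.70 ± 2.77 CPM), 6 adjusted over the list alone. Camera gave adjusted p = 0.00314 for the cytokines and 0.00424 for neutrophils (adjusted p = 0.372 with an estimated correlation for both).

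Hypoxia and glycolysis genes were lower in 16 of 20, and 4 fell, 10 adjusted over the list alone. Vegfa, the main angiogenic growth factor, had 187 ± 49.8 against 361 ± 57.5 CPM (log2 fold change -0.95), and Bnip3 (-1.18), Pdk1 (-0.40) and Tpi1 (-0.32) fell with it. This list passed camera (adjusted p = 4.60e-06) and fry (2.13e-04), with adjusted p = 0.0625 with an estimated correlation. Of 20 cell cycle genes Rrm2 (-0.62) and Mcm6 (-0.70) fell, 6 adjusted over the list alone (camera adjusted p = 0.00423, adjusted p = 0.664 with an estimated correlation). Of the cytosolic DNA sensing list the kinase gene Tbk1 (0.36, 65.6 ± 5.87 against 51.1 ± 4.05 CPM) and Zbp1 rose, also 2 adjusted over the list alone. Tmem173, which encodes STING (0.15), and Mb21d1, which encodes cGAS (-0.03), did not pass, nor did Ifng, Prf1, Cxcl10, Ccl5, Isg15, Ifit1, Cd274 or Foxp3. Ifnb1 had 7 counts in all libraries and Trex1 was listed at 0, so neither was tested. A 0 can also come from how overlapping genes were counted, so it is not read as absence of Trex1 transcripts.

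The other 18 tested lists did not pass camera (adjusted p = 0.0541 to 0.986). They were checkpoint and exhaustion, regulatory T cells and suppressive mediators, dendritic cells, macrophages and monocytes, cytosolic DNA sensing, mismatch repair, p53 and DNA damage, and chromosome segregation. Colon epithelium, enteric neurons and glia, fibroblasts and matrix, adipocytes, mesothelium, skeletal muscle, liver, erythroid cells, sex-linked genes and immediate early genes were the rest. Of these, colon epithelium passed with the plain block (camera adjusted p = 0.0468), and colon epithelium and mismatch repair with a block within each tumour type (0.0446 for both). With fry, 9 lists passed, among them mast cells, endothelium, type I interferon response and hypoxia.

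The count of 1089 genes was 1778 with the replicate number as a block, 3428 with a block within each tumour type, 2295 with DESeq2, and 135 in an additive model without the 5 libraries rich in skeletal muscle transcripts, 134 of them among the 1089. Of the genes above, Fst, Apod, Gxylt2, Cdh26, Omd, Amigo2, Ngfr, Esx1, Nrn1, Gm10392, Wnt10a, Sh3tc2, Zbp1, Il11, Cxcl3, Cxcl2 and Il6 stayed among the 135. Leaving out a library gave 1758 genes without MSI tumour CIN micronuclei 1 and fewer without most others: MSI tumour MSI micronuclei 1 (485) and 2 (495), MSI tumour MSI free 2 (583), MSI tumour CIN free 2 (669), CIN tumour CIN micronuclei 1 (542) and 2 (609), CIN tumour CIN free 1 (675) and 2 (490), CIN tumour MSI free 2 (477) and CIN tumour MSI micronuclei 2 (723).

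The DNA source comparison asked whether DNA from MSI or CIN cells, given through dendritic cells, left different tumours. Type I interferon genes were lower with MSI DNA in all 34 members, at a median log2 fold change of -0.29. Oas3, which encodes an antiviral RNA-sensing enzyme, had 42.9 ± 7.80 CPM with MSI and 58.4 ± 19.2 CPM with CIN DNA (SD, n = 8 each), and Ifit1 had 34.0 ± 9.25 and 45.3 ± 14.8 CPM. T cell genes were lower in 19 of 20 members, with a median of -0.31, and Cd8a had 19.95 ± 4.99 and 23.4 ± 3.66 CPM. MHC class I genes were lower in 20 of 20 members, with a median of -0.16. None of these members passed over all genes or adjusted over the list alone, and Oas3 was picked after its values were seen.

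With edgeR 0 of 18777 genes passed for DNA source, and 209 had an unadjusted p under 0.05. DESeq2 called 0, with 249 unadjusted. Camera at the preset correlation called 9 lists, of which 0 held with an estimated correlation and 0 with fry. For type I interferon genes the preset value was 2.17e-23 (adjusted p = 0.138 with an estimated correlation), and for T cell and MHC class I genes 7.89e-13 and 1.09e-09 (adjusted p = 0.268 with an estimated correlation for both). The interferon score was 4.91 ± 0.33 with MSI and 5.20 ± 0.35 with CIN DNA (n = 8 each, exact permutation p = 0.0432, adjusted 0.547). In CIN tumours it was 4.36 and 4.57 with MSI micronuclei and 4.88 and 5.37 with CIN micronuclei. With free DNA there it was 4.88 and 5.02 for MSI and 5.01 and 4.92 for CIN DNA. In MSI tumours its mean was lower with MSI DNA for both forms. The CIN tumour libraries with MSI micronuclei were among those rich in skeletal muscle transcripts. Libraries of mice given MSI DNA were shallower, at 13.7 ± 1.86 M against 15.7 ± 1.63 M counts (n = 8 each, exact permutation p = 0.0123, adjusted 0.469).

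The DNA form comparison set free cytosolic DNA against micronuclei. Averaged over tumour type and DNA source, all 34 type I interferon genes were higher with free DNA, at a median log2 fold change of 0.28. In CIN tumours given CIN DNA the mean interferon score was instead lower with free DNA. It was 5.01 and 4.92 with free DNA and 4.88 and 5.37 with micronuclei in replicates 1 and 2. The antiviral gene Rsad2 had 20.3 ± 4.89 CPM with free DNA and 14.2 ± 3.995 CPM with micronuclei (SD, n = 8 each), and Ifit1 had 45.4 ± 13.9 and 33.9 ± 10.4 CPM. Inflammatory cytokine genes were higher in 20 of 24 members, at a median of 0.31. Both lists passed camera (adjusted p = 1.38e-32 and 1.41e-12), and also with an estimated correlation (adjusted p = 0.0319 with an estimated correlation for both). That second call was lost for both under most alternatives, among them DESeq2 size factors (0.0575 for both) and no filter on low counts (0.183 for both). MHC class I genes were higher in 20 of 20 and interferon gamma response genes in 23 of 23 members (camera adjusted p = 3.76e-09 and 2.73e-11, adjusted p = 0.293 and 0.5256 with an estimated correlation).

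No single member passed over all genes or adjusted over the list alone. With edgeR 0 of 18777 genes passed for DNA form (148 at an unadjusted p under 0.05, DESeq2 0 with 198), and fry called 0 lists, with 0.278 for both lists. The interferon score was 5.21 ± 0.31 with free DNA and 4.91 ± 0.36 with micronuclei (n = 8 each, exact permutation p = 0.0448, adjusted 0.806). Of the other alternatives, interferon and cytokine genes gave adjusted p = 0.0948 and 0.215 with an estimated correlation under the smooth muscle covariate, 0.236 and 0.136 with summed libraries, 0.118 and 0.214 with a block within each tumour type, 0.375 and 0.518 with tissue covariates, and 0.476 for both without the 5 libraries, where the interferon median fell to 0.18. The additive model kept both calls (0.0182 and 0.00608), and the plain block kept interferon (0.0319) but not the cytokines (0.0728).

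**Figure D3:**
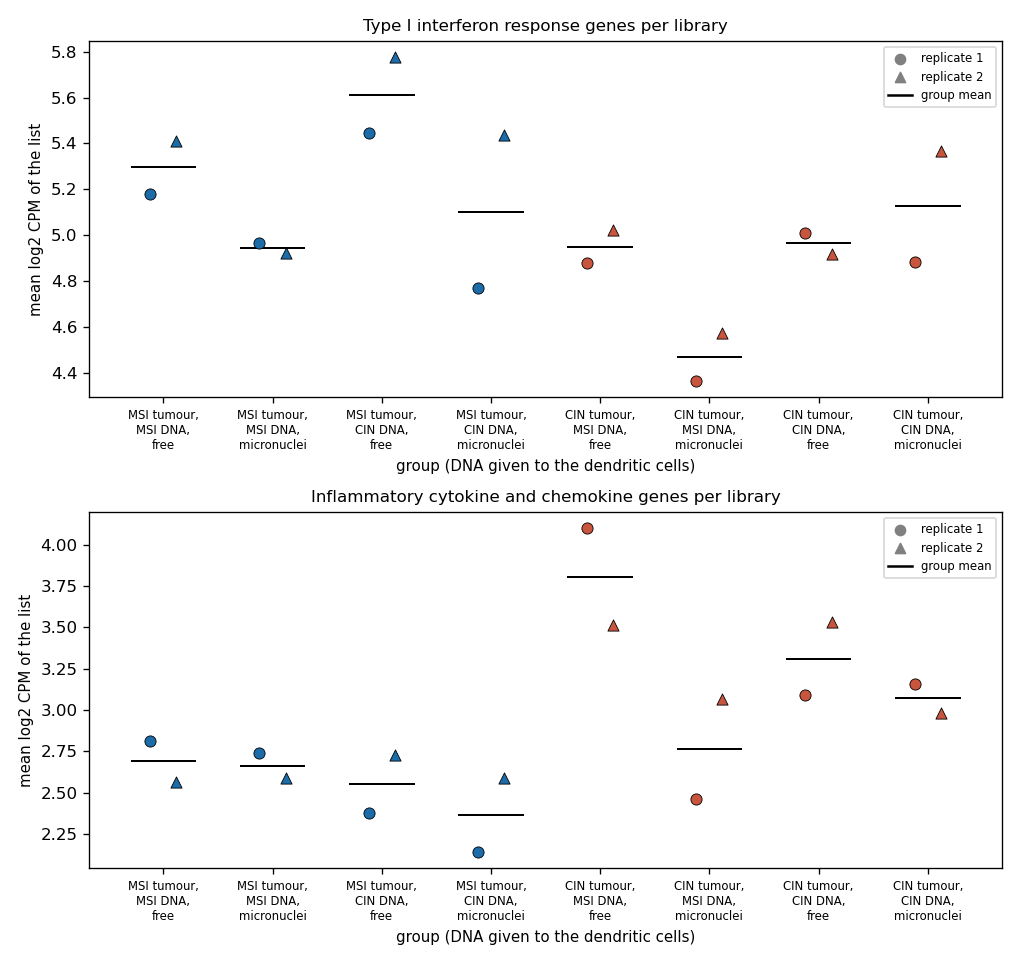
Mean log2 CPM of the type I interferon response list (upper panel) and of the inflammatory cytokine and chemokine list (lower panel) in each library, by group; circles are replicate 1, triangles replicate 2, and lines are the means of the 2 libraries. In MSI tumours the interferon score averages 5.45 with free DNA and 5.02 with micronuclei, and in CIN tumours the cytokine score averages 3.56 and 2.92.

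Within MSI tumours the type I interferon genes were higher with free DNA than with micronuclei in 34 of 34 members, at a median of 0.46. Zbp1 had 123 ± 17.0 against 81.8 ± 21.1 CPM, Oasl2 203 ± 55.6 against 136 ± 35.1 CPM and Isg15 37.2 ± 9.10 against 26.4 ± 6.63 CPM (SD, n = 4 each). The list passed camera (adjusted p = 1.34e-40, adjusted p = 0.0261 with an estimated correlation), and its score was 5.45 ± 0.24 against 5.02 ± 0.29 (n = 4 each, exact permutation p = 0.0857, adjusted 0.946, and p = 0.0556 within the DNA source groups, the smallest possible there). Within MSI tumours the score also differed by replicate number, at -0.30 for replicate 1 minus replicate 2 (exact permutation p = 0.25 within the groups). Neither permutation of the form effect used the replicate numbers. By replicate number the score with free DNA and micronuclei was 5.18 against 4.97 and 5.41 against 4.92 for MSI DNA. For CIN DNA it was 5.45 against 4.77 and 5.78 against 5.44. This pairing was not tested. In CIN tumours 31 of 34 members of the list were higher with free DNA, at a median of 0.10 (camera adjusted p = 6.38e-04, adjusted p = 0.864 with an estimated correlation). There the score with free DNA and micronuclei was 4.88 against 4.36 and 5.02 against 4.57 for MSI DNA. With CIN DNA the values were 5.01 against 4.88 and 4.92 against 5.37, so the direction differed between replicates. The test of the difference between tumour types gave a median of 0.17 (camera adjusted p = 2.33e-11, adjusted p = 0.411 with an estimated correlation). Skeletal muscle genes were lower with free DNA in MSI tumours in 11 of 11 members, at a median of -2.18 (camera adjusted p = 0.00927, adjusted p = 0.736 with an estimated correlation), and missed the threshold with the plain block (0.0549). That difference rested on MSI tumour CIN micronuclei 1, since the difference of mean scores was -1.56 with it and 0.01 without it. With an estimated correlation the call of the interferon list in MSI tumours was lost with DESeq2 size factors (adjusted p = 0.0604), no filter (0.240), the smooth muscle covariate (0.0568), tissue covariates (0.163), a block within each tumour type (0.0949), MSI tumours fitted alone (0.167) and without MSI tumour CIN micronuclei 1 (0.403), and kept with the plain block (0.0221).

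Within CIN tumours the cytokine and chemokine genes were higher with free DNA in 22 of 24 members, at a median of 0.43. The neutrophil attractant gene Cxcl1 had 63.0 ± 61.9 against 13.2 ± 3.20 CPM, Il6 14.9 ± 17.0 against 2.52 ± 1.17 CPM and Cxcl2 18.7 ± 9.67 against 6.30 ± 1.53 CPM (SD, n = 4 each). Without CIN tumour MSI free 1 the means with free DNA were 32.9 CPM for Cxcl1, 6.61 CPM for Il6 and 14.7 CPM for Cxcl2. None of the members passed over all genes or adjusted over the list alone. The list passed camera (adjusted p = 1.44e-16, adjusted p = 0.0283 with an estimated correlation), and its score was 3.56 ± 0.41 against 2.92 ± 0.31 (n = 4 each, exact permutation p = 0.0571, adjusted 0.724, and p = 0.111 within the DNA source groups). With an estimated correlation the call was lost with the plain block (adjusted p = 0.0551), a block within each tumour type (0.132), no filter (0.0835), tissue covariates (0.300) and CIN tumours fitted alone (0.363), and kept with DESeq2 size factors (0.0337) and the smooth muscle covariate (0.0363). In MSI tumours 14 of 24 members were higher, at a median of 0.08 (camera adjusted p = 0.011, adjusted p = 0.443 with an estimated correlation). There the difference of mean scores was 0.107 and turned negative without MSI tumour CIN micronuclei 1. The difference between tumour types had a median of -0.14 (camera adjusted p = 0.0064, adjusted p = 0.767 with an estimated correlation).

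At the level of single genes edgeR called 0 genes for the form effect in MSI tumours (126 at an unadjusted p under 0.05, DESeq2 0) and in CIN tumours (153, DESeq2 0). For the source effect it called 0 in MSI tumours (151, DESeq2 0) and in CIN tumours (315, DESeq2 1, the ephrin receptor gene Epha3). MSI free DNA against CIN micronuclei, the pair of stimuli that differ in both source and form, gave 0 genes in MSI tumours (121, DESeq2 1, the keratin gene Krt14, where 3% of simulated 2-fold changes were recovered) and in CIN tumours (155, DESeq2 2, Epha3 and the skeletal muscle myosin gene Myh1). The tumour by source interaction gave 0 (285, DESeq2 2, Epha3 and Scgb2b15), tumour by form 0 (159, DESeq2 0) and source by form 0 (355, DESeq2 1, the apelin receptor gene Aplnr). The genes called by DESeq2 alone were named after their values were seen.

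In the source effect within CIN tumours, B and plasma cell genes were lower with MSI DNA in 17 of 17 members, at a median of -1.51, and skeletal muscle genes higher in 11 of 11, at a median of 2.30. Neither list held (adjusted p = 0.320 and 0.418 with an estimated correlation). The difference of mean scores for B and plasma cells was -1.66, and -0.68 without CIN tumour MSI micronuclei 1. For skeletal muscle it was 1.94, against 3.14 without CIN tumour MSI free 1 and 3.04 without CIN tumour CIN free 2. In MSI tumours fibroblast and matrix genes were higher with MSI DNA in 16 of 20 members (median 0.20) and hypoxia genes lower in 20 of 20 (median -0.18), both with adjusted p = 0.0964 with an estimated correlation. Camera at the preset correlation called 10 to 22 lists in the 4 effects within a tumour type, 12 and 19 in the pair comparisons and 12 to 17 in the interactions. With an estimated correlation 1 held in each form effect within a tumour type, and 0 in the others.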

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

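Each measure was tested for a library far from the other 7 of its tumour type (Dixon's ratio, at 0.05). Of 194 tests 12 passed, where about 1 in 20 would by chance. The interactions were looked at by their lists with an estimated correlation, a criterion chosen after their counts at the preset correlation (15, 12 and 17) had been seen.

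CIN tumour MSI micronuclei 1 stood below the other CIN tumours for colon epithelium (ratio 0.675, score 2.13, nearest 6.13), liver (0.683, -1.19, nearest 1.28), mesothelium (0.633, -0.54, nearest 1.47) and exocrine pancreas genes (0.593, 0.41, nearest 1.93). It was also lowest for B and plasma cell genes (0.589, -0.87, nearest 2.44), smooth muscle (0.587, 1.47, nearest 3.41) and sex-linked genes (0.537, 1.70, nearest 2.54). MSI tumour CIN micronuclei 1 stood above the other MSI tumours for skeletal muscle genes (0.725, 5.66, nearest 0.62). CIN tumour CIN micronuclei 2 had the highest immunoglobulin share (0.591, 0.353%, nearest 0.145%) and the lowest log2 CPM of Rrm2, a nucleotide reductase gene of dividing cells (0.627, 6.56, nearest 7.22). Klrk1, a receptor gene of killer cells, was lowest in MSI tumour MSI micronuclei 1 (0.570, 2.18, nearest 2.91), and Cd8a in MSI tumour MSI micronuclei 2 (0.681, 3.72, nearest 4.48). No explanation of these single libraries was tested.

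Among the 3 interactions edgeR called 0 genes (159 to 355 at an unadjusted p under 0.05, DESeq2 0 to 2), and 0 lists passed with an estimated correlation.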

How the results depend on the processing

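The permutations within the groups of a tumour type, the block within each tumour type, the colon epithelium and skeletal muscle covariates and the fit without the 5 libraries rich in skeletal muscle were chosen after seeing the data. The other alternatives, the comparisons and the lists were chosen before the data were examined. The cause of each change in a count was not tested.

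The 1089 genes of the tumour effect became 1778 with the replicate number as a block (1087 shared), 3428 with a block within each tumour type (1089 shared), 1963 with the smooth muscle covariate (1086 shared) and 1950 in the additive model (1074 shared). Summing the libraries of each group gave 2836 (990 shared), DESeq2 2295 (1089 shared), and leaving out the 5 libraries 135 (134 shared). Without the filter on low counts 286 genes were higher and 793 lower, 26.5% higher against 39.9%. Without single libraries the count was 1758 (MSI tumour CIN micronuclei 1), 485 and 495 (MSI tumour MSI micronuclei 1 and 2), 583 (MSI tumour MSI free 2), 669 (MSI tumour CIN free 2), 542 and 609 (CIN tumour CIN micronuclei 1 and 2), 675 and 490 (CIN tumour CIN free 1 and 2), 477 (CIN tumour MSI free 2) and 723 (CIN tumour MSI micronuclei 2).

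For the source effect in MSI tumours the tissue covariates gave 1 gene (Ces2d-ps). DESeq2 called 2 genes for tumour by source, 1 for source by form, 1 for the source effect in CIN tumours, and for MSI free DNA against CIN micronuclei 1 in MSI and 2 in CIN tumours.

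With an estimated correlation the lists passing numbered 0 for the tumour effect, 0 for DNA source, 2 for DNA form, 1 for form in MSI tumours, 1 for form in CIN tumours, and 0 for the source effects within tumours, the pairs and the interactions. With fry they numbered 9 for the tumour effect and 0 for every other comparison. The type I interferon median for DNA source was -0.29 (adjusted p = 0.138 with an estimated correlation, fry 0.434). For DNA form the interferon median was 0.28 and the cytokine median 0.31 (fry 0.278 for both), for form in MSI tumours the interferon median was 0.46 (fry 0.228), and for form in CIN tumours the cytokine median was 0.43 (fry 0.192). The calls with an estimated correlation were mostly lost: DNA form with DESeq2 size factors (0.0575 for both lists), no filter (0.183 for both), the smooth muscle covariate (0.0948 and 0.215) and summed libraries (0.236 and 0.136), form in MSI tumours with DESeq2 size factors (0.0604), no filter (0.240) and its own libraries (0.167), and form in CIN tumours with no filter (0.0835), tissue covariates (0.300) and its own libraries (0.363). Form in MSI tumours kept its call with the replicate block (0.0221), and form in CIN tumours with DESeq2 size factors (0.0337) and the smooth muscle covariate (0.0363). For DNA form the interferon list stayed under 0.05 only without CIN tumour CIN micronuclei 1 (0.0452) or 2 (0.0186), and the cytokine list only without CIN tumour CIN micronuclei 1 (0.0452), when 1 library was left out. Leaving out 1 library, the adjusted p of the interferon list for form in MSI tumours with an estimated correlation ran from 0.0173 (CIN tumour CIN micronuclei 2) to 0.403 (MSI tumour CIN micronuclei 1), and stayed under 0.05 only without CIN tumour CIN micronuclei 1 or 2 or CIN tumour MSI free 1 or 2. The cytokine list in CIN tumours ran from 0.0324 (CIN tumour CIN micronuclei 1) to 0.254 (CIN tumour MSI micronuclei 2), and stayed under 0.05 only without CIN tumour CIN micronuclei 1, CIN tumour CIN free 1, CIN tumour MSI free 2, MSI tumour CIN free 1 or MSI tumour MSI micronuclei 2. For DNA source the interferon list passed only without CIN tumour CIN micronuclei 1 (0.0476).

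Genes that did not pass changed sign in the tumour effect. Mb21d1 (-0.03) had 0.0798 with the smooth muscle covariate, 0.12 with the colon and skeletal covariates, 0.16 without the 5 libraries, and -0.12 to 0.10 without single libraries. Without single libraries Gzmb ran from -0.0301 to 0.31, Prf1 from -0.18 to 0.26 and Ccl5 from -0.22 to 0.0308.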

Other observations

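The tests of the ribosomal protein share below were chosen only after the result was seen, and the genes of this paragraph were picked after their values were seen. Some matrix genes were lower in MSI than in CIN tumours, though the fibroblast and matrix list did not pass camera (9 of 20 members positive, adjusted p = 0.0589, fry 0.0498, score 6.67 ± 0.24 against 6.85 ± 0.38, n = 8 each, exact permutation p = 0.301). Col1a1, the main chain of type I collagen, had 353 ± 81.3 against 923 ± 169 CPM (SD, n = 8 each, log2 fold change -1.39 ± 0.12, edgeR with Benjamini-Hochberg adjusted p = 2.59e-04), and Col5a1 (-1.04), the pericyte receptor gene Pdgfrb (-1.06) and the collagen cross-linking gene Loxl2 (-0.59) fell with it. Of the enteric neuron and glia list 2 genes fell while 13 of 17 members were positive and the list did not pass (camera adjusted p = 0.442): the tubulin gene Tubb3 had 222 ± 73.0 against 561 ± 82.0 CPM, and the adhesion gene L1cam 46.4 ± 16.05 against 137 ± 21.01 CPM. Tgfb1 (-0.77) and Nos2 (-1.26) were lower in MSI tumours. Their list of regulatory T cell and suppressive genes had 8 of 13 members negative and did not pass camera (adjusted p = 0.0602, fry 0.0063), while its score differed (3.51 ± 0.11 against 3.78 ± 0.10, n = 8 each, exact permutation p = 0.00154, adjusted 0.0293). Msln, a mesothelial surface protein gene, was higher (141 ± 68.7 against 32.0 ± 5.75 CPM), but 6 of 9 members of the mesothelium list were negative (camera adjusted p = 0.986). Whether these transcripts came from the tumour cells or from host cells was not tested.

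Stress genes, also picked after their values were seen, moved both ways, and neither the p53 list (14 of 22 positive, camera adjusted p = 0.599) nor the immediate early list (11 of 22, 0.281) passed. Of the genes called by edgeR, in the p53 list Phlda3 (-1.02) and Gadd45g (-0.76) were lower in MSI tumours while Sesn1 (0.60) and Plk3 (0.57) were higher. Of the immediate early genes Egr3 (-1.25) and Junb (-0.49) were lower and Dusp1, a phosphatase gene, higher (0.86). Cenpf, a kinetochore gene, was lower (-0.76).

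The genes called between MSI and CIN tumours were weighed against colon and muscle tissue in the sample, a single library and chance. Differences between the MSI and the CIN line other than the kind of instability could not be weighed, with 1 line per type. With the colon epithelium and skeletal muscle scores as covariates the fold changes kept a median ratio of 0.945 to those without. The quartiles were 0.872 and 1.02, and 1089 of 1089 kept the same sign. The colon epithelium score also differed between the 2 libraries of every group. A gene that follows it spreads widely within groups and is less likely to be called. A ratio near 1 was therefore likely among called genes, so it cannot decide whether these tissues were a cause. It shows only that the fold changes of the called genes depended little on these scores. Without CIN tumour MSI free 2, the library with the largest loss, 470 genes were still called, which leaves open how far the rest depend on it. Of 100 splits of the libraries into 8 and 8 in a model of the split alone, 1, the real one, called as many as its 2471 genes. The highest other called 1. That argues against chance for the gene count of that model, which is not the fit with 1089 genes. It does not exclude chance, since 100 splits show no share under 1 in 100. The splits also took the 2 libraries of a group as independent, and the other splits held the tumour difference in their spread, which can lower their calls. For the number of lists chance remains possible, since 36 of 100 splits gave at least the real 13, the highest other 21.

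For the other comparisons the gene counts cannot be weighed by splits. The DNA source, DNA form and 3 interaction splits called 0 genes with edgeR (highest other 1), and since every split calls at least 0, 100 of 100 was bound to result. The fits reported had 148 to 355 genes at an unadjusted p under 0.05, and DESeq2 0 to 2 calls. For the numbers of lists chance cannot be excluded. At least the real number came from 71 of 100 splits for DNA source (real 9), 51 for DNA form (11), 36 for tumour by source (13), 41 for tumour by form (12) and 51 for source by form (11), with 21 as the highest other. The other splits had a median of 11 lists. Within each tumour type the real gene count was 0 too, so 35 of 35 splits as large says nothing (126 to 315 at an unadjusted p under 0.05 in the fits reported, DESeq2 0 to 1). In MSI tumours the split by replicate number called 7807 genes, and in CIN tumours a split that sets the 3 replicate 2 libraries rich in skeletal muscle and CIN tumour MSI micronuclei 1 apart called 2559, which points to a structure of the samples. Among the 18 splits of MSI tumours with equal numbers of replicate 1 libraries on each side, as in the real ones, the highest was 0. For lists, 2 of 35 splits in MSI tumours gave at least the real 15 for source (highest other 16) and 6 at least the real 13 for form (16). In CIN tumours 3 gave at least the real 17 for source (22) and 22 at least the real 10 for form (22).

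The higher interferon genes with free DNA in MSI tumours were weighed against tissue, T cell content and a single library. With the 2 tissue scores as covariates the median ratio of fold changes was 0.919 (quartiles 0.850 to 1.08), and with the T cell score 1.04 (0.918 to 1.14), which argues against each as the whole cause. The lowest median with a library left out was 0.37, without MSI tumour CIN micronuclei 1, so no single library was the whole cause. The call was lost with DESeq2 size factors (adjusted p = 0.0604 with an estimated correlation), with the tissue covariates (adjusted p = 0.163 with an estimated correlation) and without that library (0.403), while the medians were 0.47, 0.40 and 0.37. A hypothesis left open is that dendritic cells given free DNA may leave a stronger interferon response in MSI tumours, but the difference between tumour types did not pass (adjusted p = 0.411 with an estimated correlation).

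Ribosomal protein genes took a larger share of counts in replicate 1 than in replicate 2 in 8 of 8 groups, by 0.694 ± 0.250 percentage points (SD, n = 8 groups). More normal colon in replicate 2, as the whole cause, would allow no group with both the share and the colon epithelium score higher in replicate 1. There were 2 such groups, CIN tumour MSI free and CIN tumour CIN free, which argues against it. An exact sign-flip test gave p = 0.00781, the smallest possible with 8 groups. A library batch that goes with the replicate number cannot be told apart from different animals, since the labels give neither.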
